A study of Rattus norvegicus with 12 samples.

How the data were processed

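The values analysed were the deposited normalized read counts of the authors, in which the signal of a gene in a library is its number of reads divided by the size factor of that library. The submitters' processing notes name Trimmomatic, Bowtie2, TopHat2, HTSeq and DESeq2, and reads placed on the rat genome build Rnor_6.0, with the versions and exact settings not given in the sources used here. Libraries were made with a stranded mRNA kit (TruSeq) from 1000 ng of RNA purified on RNeasy columns and sequenced on an Illumina instrument. The table held 15939 genes in 12 libraries, coded by age (Y young, A aged), by group (N nonperforming, P performing) and by replicate, from YN1 to AP3. Dividing each library by its smallest step gave whole numbers for 100% of values within a tolerance of 0.01, so the reads behind each value were recovered, and they totalled from 22189094 in AP1 to 42205582 in YP3. Gene positions are left out, since no genome was given and the gene table given describes another build (GRCr8) than the one the reads were placed on. Each of 2 symbols belonged to more than 1 Ensembl identifier, and these were kept apart by identifier.

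Genes with a value of at least 10 in at least 3 libraries were kept (13496 genes), and 1 was added before the log2. A single limma fit of 4 group means (limma 3.58.1 in R 4.3.3, trend on, residual degrees of freedom 8, prior degrees of freedom 3.3) gave 7 contrasts: age and performance averaged over the other factor, each within the levels of the other, and their interaction. All tests were two-sided, p-values were adjusted by Benjamini and Hochberg over the genes tested in each contrast, and an adjusted p under 0.05 counted as passing. The design, the fit, the 34 gene lists and most alternatives were fixed before the data were examined. Lists were tested with cameraPR of limma at a preset correlation of 0.01 between genes, and again with a correlation estimated from the data, with the rotation test fry and by exact permutation of library scores. The preset treats the members of a list almost as independent, so calls made with it state a shared direction beyond other genes and not a difference beyond the spread of correlated genes. The lists named 793 distinct genes, of which 732 matched the table (some through RefSeq synonyms, such as Slco1a4, listed as Slco1a2) and 709 were tested. The median change of a list is that of its tested members, and its score in a library is the mean over members of the log2 value minus the gene's mean over all libraries. Further lists, 3 in number, were added after the data were seen: olfactory bulb score genes (10 listed, 8 tested), other olfactory bulb genes seen in the main variation, and long transcript genes. Only the interaction, which compares differences, was not tested by permutation.

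Genes were named by fixed rules. In each contrast the 10 largest rises and falls among passing genes with a mean of at least 50 were to be named, and where fewer than 5 passed, the 5 genes with the smallest p were named and said not to have passed. Up to 4 members per called list were available for naming, and Fos, Arc, Egr1, Npas4, Bdnf, Gfap, Mbp and Aif1 were always given. Some members of called lists are not reported here. A list value without a call that changed sign under an alternative counted as unchanged. Dixon's test was not applied to groups of 3. No paired analysis was possible because the replicate numbers follow only the order of the samples and the labels state no pairs. The alternatives were other pseudocounts (0.5 and 5), no filter, a stricter filter (mean of at least 50), TMM rescaling, quantile normalization, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 Wald tests on the recovered reads, library quality weights, robust variance shrinkage (statmod 1.5.0), the title prefix as a covariate (2 libraries, YN1 and YP1, carry VP and the other 10 carry U), an additive model, only the libraries compared, a threshold of 0.1, and leaving out each library in turn. Alternatives without YP2, AP1 and AP3, without these and YN3, and with the olfactory bulb score as a covariate were added after the data were seen.

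Known changes were placed in simulated tables built with the dispersion of the real data, all 13496 genes run. Each gene was drawn on its own from a profile common to all libraries. The simulated tables therefore held no outlying library and no correlation between genes, unlike the real ones. The shares recovered do not tell which changes the real data could show. For age averaged over performance, limma recovered 76.1, 92.5 and 97% of genes changed by log2 1, 2 and 3, with 7 false among 184 calls. For performance averaged over age it recovered 76.1, 89.6 and 97%, with 8 false among 183 calls. For age in nonperforming rats it recovered 40.3, 86.6 and 97%, with 7 false among 156 calls, and for performance in young rats 49.3, 85.1 and 93.9%, with 2 false among 154 calls.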

Results

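Gene expression in the medial prefrontal cortex, the part of the frontal cortex that serves attention in rodents, was measured in 12 RNA sequencing libraries from Wistar rats. The rats were young (3 months) or aged (22 months), and within each age they were performing or nonperforming. Performing rats had learned an operant task and were tested on attention in it, and nonperforming rats of the same age shared the setting but never did the task. Each of the 4 groups held 3 libraries, which are named YN1 to YN3 (young nonperforming), YP1 to YP3 (young performing), AN1 to AN3 (aged nonperforming) and AP1 to AP3 (aged performing). The table held 26937210, 24992397 and 36657127 reads for YN1, YN2 and YN3, and 26874737, 22632924 and 42205582 for YP1, YP2 and YP3. It held 22597857, 26460306 and 26726780 reads for AN1, AN2 and AN3, and 22189094, 22338950 and 25366318 for AP1, AP2 and AP3. Differences between libraries exceeded counting error in every pair (chi-squared per degree of freedom from 7.2 to 456), so the spread between libraries, and not the depth, set the precision of most values. Gene p-values measure spread between libraries, not known to be separate animals, and preset camera p-values spread between genes. Values are normalized read counts, as mean ± SD of 3 libraries, and changes are on the log2 scale.

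Several libraries carried RNA of genes that mark tissue next to the medial prefrontal cortex or other cell types, and these genes are given first because they move with the groups. Cdhr1, a cadherin of olfactory bulb projection neurons, stood at 6016 in YP2, 5231 in AP1 and 8405 in AP3, at 1866 in AP2 and 855.5 in YP3, and between 296.6 and 493.2 in the other 7 libraries. Th, the rate-limiting enzyme of dopamine synthesis and a marker of olfactory bulb interneurons, stood at 648.2, 422.5 and 883.3 in YP2, AP1 and AP3, at 137.6 in AP2 and 94.2 in YP3, and at 73.87 or less elsewhere. An olfactory bulb score, the mean log2 value of 8 tested bulb genes chosen after the data were seen, averaged 6.48 ± 0.17 in young nonperforming and 6.69 ± 0.08 in aged nonperforming rats, against 7.51 ± 1.24 in young performing and 8.48 ± 1.07 in aged performing rats (SD, n = 3). The performing libraries were higher by 1.41 on average over both ages, a difference given without a test because its genes were chosen from these data. Mitochondrially encoded genes took 21 ± 2.2% and 23.3 ± 3.7% of the reads in young and aged performing rats, against 16.4 ± 4.8% and 17.5 ± 3.2% in young and aged nonperforming rats (difference of 5.25 points, two-sided exact permutation p = 0.01 within ages, where 0.005 is the smallest possible). Ttr, the transthyretin gene of the choroid plexus, stood at 37300 in YN3 and at 91.88 or less in the other 11 libraries. YN3 also had the lowest mitochondrial share (10.8%, against 13.9 to 27.6% elsewhere), the lowest median rank correlation with the other libraries (0.93, against 0.974 to 0.988), and the highest value of all 12 libraries for 4089 of the 13496 genes tested. Cd74, the invariant chain of MHC class II, stood at 38920 in AP2 and at 2915 or less elsewhere. The hemoglobin gene Hbb stood at 16900 in AN3 and at 7909 or less elsewhere, and the striatal dopamine receptor gene Drd2 at 380.5 in AN3 and 301.1 in YP3 against 132.4 or less elsewhere.

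**Figure D1:**
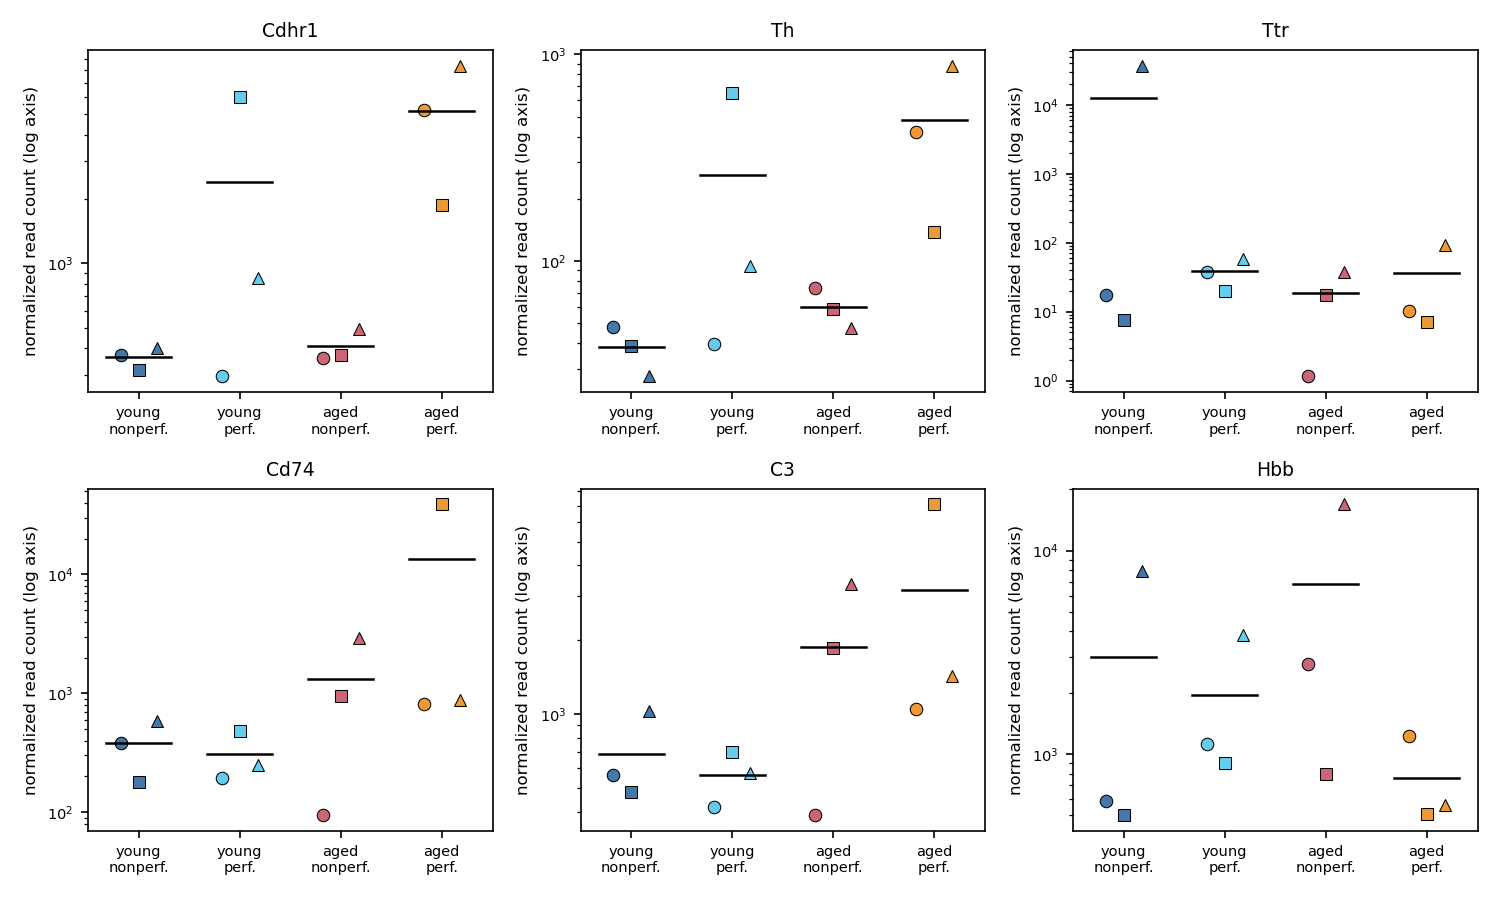
Normalized read counts (log axis) of Cdhr1, Th, Ttr, Cd74, C3 and Hbb by group, with 1 point per library (circle, square and triangle for replicates 1, 2 and 3) and a line at the arithmetic mean of the 3 libraries. Cdhr1 was highest in YP2, AP1 and AP3, Ttr reached 37300 in YN3 and Cd74 38920 in AP2.

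**Figure D2:**
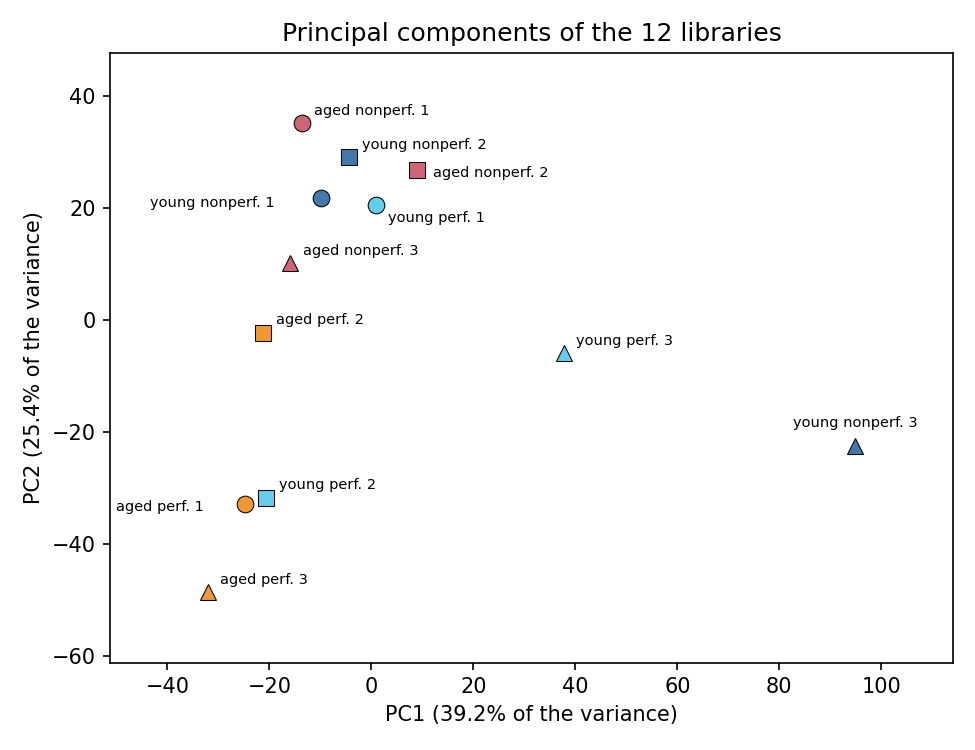
First and second principal components of the log2 values of the 12 libraries, in arbitrary units, with 39.2% and 25.4% of the variance. YN3 lies at 94.9 on the first component, and YP2, AP1 and AP3 lie between -48.6 and -31.7 on the second.

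The average effect of age asked which genes differed between the 6 aged and the 6 young libraries, whatever their performance. Genes of complement and antigen presentation, the pathways that tag material for removal and display peptides to T cells, rose as a list in aged rats, with a median change of 0.56 and 30 of 31 members higher (camera adjusted p = 2.7e-07, and adjusted p = 0.94 with an estimated correlation). C3, the central complement protein, averaged 688 ± 292 and 564 ± 143 in young nonperforming and young performing rats, against 1860 ± 1480 and 3190 ± 3390 in aged nonperforming and aged performing rats (SD, n = 3). C4b averaged 30.7 ± 9.85 and 30.1 ± 13.5 against 84.3 ± 35.8 and 181 ± 221. AP2 had by far the highest score of this list (2.03, against 0.822 or less in the other libraries), and the list kept its call without any 1 library, with a median between 0.39 and 0.78. Genes of the mitochondrial respiratory chain encoded in the nucleus fell as a list by 0.22, with 40 of 42 members lower in aged rats (adjusted p = 5e-07, and adjusted p = 0.94 with an estimated correlation). Uqcrfs1, the iron-sulfur subunit of complex III, averaged 4350 ± 1390 and 3830 ± 543 in young against 2970 ± 188 and 3540 ± 179 in aged rats. YN3 carried much of that change, since the median was -0.07 without it (adjusted p = 0.00062).

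Endothelial and pericyte markers also fell as a list with age, by 0.37 with 16 of 17 lower (adjusted p = 0.00018, and adjusted p = 0.94 with an estimated correlation). Its median was -0.19 without YP3. Tie1, an endothelial receptor kinase, averaged 907 ± 126 and 793 ± 310 in young against 581 ± 165 and 508 ± 25.5 in aged rats. Glucocorticoid responsive genes rose by 0.27, with 18 of 21 higher (adjusted p = 0.00029, and adjusted p = 0.94 with an estimated correlation). Pdk4 and Sgk1, 2 of them, passed when adjusted over the list alone, against 0 over all genes tested. Pdk4, a kinase that restrains pyruvate oxidation, averaged 60.9 ± 8.82 and 115 ± 33.2 in young against 154 ± 79.7 and 187 ± 9.86 in aged rats. The stress-induced kinase gene Sgk1 averaged 1240 ± 318 and 1580 ± 374 against 3660 ± 2430 and 2260 ± 428. Heat shock and protein folding genes fell by 0.22 with 23 of 28 lower (adjusted p = 0.0057, and adjusted p = 0.94 with an estimated correlation). That call was lost without YN3 (-0.14), YP3 (-0.14) or AN1 (-0.12). Chordc1, a partner of the chaperone Hsp90, averaged 1330 ± 65.2 and 1240 ± 216 in young against 1120 ± 168 and 1010 ± 142 in aged rats. Hspa9, the mitochondrial member of the family, ran the other way, from 2530 ± 520 and 2570 ± 127 to 3220 ± 273 and 2770 ± 196. Interferon response genes rose by 0.28 with 22 of 25 higher (adjusted p = 0.0094, and adjusted p = 0.94 with an estimated correlation). They lost the call without YN1 (0.29), YN2 (0.23), YP1 (0.21), AN3 (0.15) or AP2 (0.19), while the median was 0.53 without AN1. Immediate early genes rose by 0.23 with 23 of 36 higher (adjusted p = 0.034), and microglia markers by 0.25 with 16 of 18 higher (adjusted p = 0.047), each with adjusted p = 0.94 with an estimated correlation. Both were fragile, since 7 of the 12 fits without 1 library ended each call, with medians from 0.13 to 0.34 for the first list and from 0.04 (without AP2) to 0.37 for the second. For the immediate early genes those 7 libraries were YN1, YN2, YP1, YP2, AN1, AN2 and AP2, and for the microglia markers YN1, YN2, YP1, YP2, AN2, AN3 and AP2. With the title prefix, which sets YN1 and YP1 apart from the other libraries, as a covariate, 4 of these age calls ended, those of glucocorticoid responsive (0.19, adjusted p = 0.076), interferon response (0.18, adjusted p = 0.64), immediate early (0.14, adjusted p = 0.25) and microglia genes (0.11, adjusted p = 0.64). Immediate early genes also lost their call without YP2, AP1 and AP3 (0.16, adjusted p = 0.23), and heat shock genes lost theirs with the olfactory bulb score as a covariate (-0.14, adjusted p = 0.074) and under quantile normalization (-0.17, adjusted p = 0.053). Complement, microglia and interferon response genes were higher without those 3 libraries, at 0.98, 0.5 and 0.48, in a fit where AP2, the library highest in complement genes, is the lone aged performing one.

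Among single genes, Zfp36 (ENSRNOG00000058388), whose protein speeds the decay of inflammatory messenger RNAs, had the smallest p for age. It averaged 138 ± 14.3 and 172 ± 14.3 in young nonperforming and young performing rats, against 295 ± 39.3 and 220 ± 26.8 in aged nonperforming and aged performing rats (SD, n = 3), a change of 0.72. Aplnr (ENSRNOG00000009227), the apelin receptor of blood vessels, averaged 140 ± 24.7 and 126 ± 67.7 against 29.5 ± 24.2 and 57.3 ± 13.7. Cyp4b1, a cytochrome P450, averaged 28.5 ± 3.56 and 30 ± 8.19 against 11.5 ± 1.97 and 16.5 ± 3.25. The secreted protein gene Egfl6 averaged 116 ± 17.7 and 101 ± 12.5 against 55.5 ± 4.45 and 69.2 ± 19. Chad, a matrix protein of cartilage, averaged 6.08 ± 4.19 and 10.7 ± 2.12 against 24.3 ± 5.61 and 24.6 ± 10.6. The astrocyte filament gene Gfap averaged 14900 ± 8810 and 16900 ± 4640 in young against 25300 ± 19400 and 30700 ± 7040 in aged rats. The myelin gene Mbp averaged 133000 ± 111000 and 150000 ± 22000 against 130000 ± 63800 and 137000 ± 20700. The microglial gene Aif1 averaged 1050 ± 851 and 766 ± 180 against 589 ± 170 and 1290 ± 931. The activity-dependent genes Fos, Arc and Npas4 had average age values of 0.70, 0.68 and 0.75 and adjusted p = 0.54 each, and Egr1 and Bdnf had values of -0.14 and -0.31. With limma, 0 of 13496 genes passed an adjusted p of 0.05 (smallest adjusted p = 0.54, shared by the 5 genes named first), and 1012 had an unadjusted p under 0.05 where 675 were due by chance. At that p 12 of 100 splits of the libraries gave as many as 1012 genes. In edgeR the count was also 0. DESeq2 called 2, Zfp36 (adjusted p = 0.00014) and Aplnr (adjusted p = 0.027), and limma with library quality weights called 5. With YP2, AP1 and AP3 left out, limma called 0 genes and 549 had an unadjusted p under 0.05, and with YN3 left out as well it called 1, Plac8.

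Age was next compared within nonperforming rats, the contrast of ordinary aging without the task. Immediate early genes, which neurons switch on when active, rose as a list in aged nonperforming rats, with a median of 0.31 and 29 of 36 members higher (adjusted p = 1.2e-05, and adjusted p = 0.9 with an estimated correlation). Fos averaged 865 ± 538 in aged against 358 ± 147 in young nonperforming rats (SD, n = 3), Arc 7900 ± 3580 against 3670 ± 3060, and Npas4 722 ± 516 against 218 ± 33.6. Egr1 was at 6490 ± 2500 against 6940 ± 3770 and Bdnf at 536 ± 162 against 619 ± 37.9, so they did not follow. Dusp1, Btg2 and Trib1 passed when adjusted over the list alone, against 0 over all genes tested, and Dusp1, a phosphatase that ends MAP kinase signals, averaged 2290 ± 1050 against 923 ± 384. The list's median was 0.56 without YN3, 0.14 without AN1 and 0.51 without AN3, and it kept its call in all 12 fits without 1 library. Meningeal and fibroblast genes fell by 1.22 with 14 of 14 lower (adjusted p = 9.2e-08, and adjusted p = 0.9 with an estimated correlation). The collagen gene Col3a1 averaged 87.5 ± 12.2 against 302 ± 122. Igf2, a growth factor made in the meninges, averaged 187 ± 30.4 against 1290 ± 682. Blood cell genes rose by 1.96 with 8 of 8 higher (adjusted p = 8.4e-05, and adjusted p = 0.9 with an estimated correlation). That list rested in part on AN3, without which its median was 0.77, and it lost its call without YN2 (1.33). Its members S100a8 and S100a9, which neutrophils rather than red cells carry, averaged 459 ± 636 and 672 ± 929 in aged against 11.6 ± 4.15 and 28 ± 8.81 in young nonperforming rats.

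Endothelial and pericyte markers fell by 0.41 in aged nonperforming rats, with 15 of 17 lower (adjusted p = 0.00023, and adjusted p = 0.9 with an estimated correlation), and Vtn, the pericyte vitronectin gene, averaged 310 ± 79.8 against 804 ± 204. Glucocorticoid responsive genes rose by 0.26 with 17 of 21 higher (adjusted p = 0.00023, and adjusted p = 0.9 with an estimated correlation), and Sgk1 and Pdk4 passed when adjusted over the list alone, against 0 over all genes tested. That call ended without YN1 (0.22), and the median was 0.41 without AN2. Respiratory chain genes fell by 0.34 with 40 of 42 lower (adjusted p = 9.2e-08, and adjusted p = 0.93 with an estimated correlation). Yet the median was 0.01 without YN3 (adjusted p = 0.74) and -0.54 without YN1. Choroid plexus markers fell by 0.85 with 9 of 10 lower (adjusted p = 0.015, and adjusted p = 0.93 with an estimated correlation). That call, too, ended without YN3 (0.08) or AN2 (-0.68), while the median was -1.29 without YN1 and -1.42 without YN2. Calcium channel, store and buffer genes rose by 0.28 with 21 of 29 higher (adjusted p = 0.022, and adjusted p = 0.93 with an estimated correlation). These genes lost the call without YN3 (-0.08), AN1 (0.22) or AN2 (0.34), with medians of 0.51 without YN1 and 0.46 without YN2. Cacnb3, a calcium channel subunit of that list, ran against it, at 7710 ± 389 in aged against 10400 ± 1750 in young nonperforming rats.

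Zfp36 and Aplnr again had the smallest p among single genes in nonperforming rats, with changes of 1.09 and -2.48. Pim3, a survival kinase, averaged 985 ± 239 in aged against 571 ± 54.9 in young nonperforming rats (SD, n = 3). The secreted phospholipase gene Pla2g3 averaged 130 ± 80 against 31.3 ± 12.1, and Egfl6 55.5 ± 4.45 against 116 ± 17.7. The changes of Gfap, Mbp and Aif1 were 0.66, 0.13 and -0.59, and none of the 3 passed. In limma, 0 of 13496 genes passed (smallest adjusted p = 0.66), and 428 had an unadjusted p under 0.05 where 675 were due by chance. The edgeR count was 0 as well. DESeq2 called 7 (Zfp36, Aplnr, Pim3, Pla2g3, Mmp8, S100a8 and S100a9), and limma with library quality weights called 4. Without YP2, AP1 and AP3 limma called 0, with 285 genes at an unadjusted p under 0.05.

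In performing rats the age comparison asked how aging looked after training in the attention task. Complement and antigen presentation genes rose as a list in aged performing rats, by 0.92 with 31 of 31 members higher (adjusted p = 9.5e-16, and adjusted p = 0.84 with an estimated correlation). C2, a complement protease, averaged 330 ± 370 in aged against 53.2 ± 11.3 in young performing rats (SD, n = 3). B2m, the MHC class I light chain, averaged 19000 ± 4320 against 11800 ± 2330, and the class I gene RT1-N2 96.9 ± 58.1 against 20.6 ± 25.9. The list kept its call without any 1 library, with medians between 0.66 and 1.2, although AP2 held most of the excess (Cd74 at 38920, against 818 in AP1 and 877.4 in AP3). Microglia markers rose by 0.49 with 18 of 18 higher (adjusted p = 5.7e-05, and adjusted p = 0.84 with an estimated correlation), but the call ended without AP2 (0.13). The median was 0.31 without YP1. Tyrobp, a signalling adaptor of microglia, averaged 890 ± 427 against 460 ± 98.2, and Aif1 1290 ± 931 against 766 ± 180. Interferon response genes rose by 0.4 with 21 of 25 higher (adjusted p = 0.003, and adjusted p = 0.84 with an estimated correlation). That call was lost without YP1 (0.16) or AP2 (0.25), with a median of 0.61 without YP2. Without YP2, AP1 and AP3, which leaves AP2 as the whole aged performing group, the complement, microglia and interferon medians were 1.87, 1.05 and 0.8.

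Striatal projection neuron genes fell by 0.62 in aged performing rats with 10 of 12 lower (adjusted p = 0.0057, and adjusted p = 0.84 with an estimated correlation). The striatal call ended without YP3 (0.02), the young library with high Drd2, or without YN3 (-0.62). Respiratory chain genes fell by 0.15 with 40 of 42 lower (adjusted p = 0.0032, and adjusted p = 0.84 with an estimated correlation). This call ended without YP3 (-0.08) and was -0.23 without YP2. Heat shock and protein folding genes fell by 0.25 with 23 of 28 lower (adjusted p = 0.0045, and adjusted p = 0.84 with an estimated correlation). The list lost its call without YP3 (-0.1). Hsph1 averaged 4560 ± 818 against 6530 ± 1610. Endothelial and pericyte markers fell by 0.34 with 13 of 17 lower (adjusted p = 0.006, and adjusted p = 0.84 with an estimated correlation). Its call was lost without YP3 (0) or AP2 (-0.18) and was -0.52 without YP1. Cholinergic genes fell by 0.24 with 11 of 17 lower (adjusted p = 0.016, and adjusted p = 0.84 with an estimated correlation). The call ended without YN3 (-0.24), YP3 (-0.13) or AP3 (-0.23) and was -0.14 without YP1. In that list Chat, the enzyme that makes acetylcholine, averaged 8.04 ± 4.36 against 23.1 ± 9.29, and the nicotinic receptor gene Chrnb3 ran the other way, at 26.9 ± 18 against 10.6 ± 18.4. Glucocorticoid responsive genes rose by 0.21 with 16 of 21 higher (adjusted p = 0.016, and adjusted p = 0.84 with an estimated correlation). This call ended without YN3 (0.21), YP1 (0.11) or AP1 (0.18). Meningeal and fibroblast genes rose by 0.61 with 13 of 14 higher (adjusted p = 0.034, and adjusted p = 0.84 with an estimated correlation), in groups where YP2, AP1 and AP3 also carried the bulb genes. That call ended without YN3 (0.61), YP1 (-0.02), AP1 (0.56) or AP3 (0.16), and its median was 1.29 without YP2, 1.24 without AP2 and -0.24 with the olfactory bulb score as a covariate. Excitatory neuron markers fell by 0.17 with 12 of 18 lower (adjusted p = 0.048, and adjusted p = 0.84 with an estimated correlation), a call kept in only 4 of the 12 fits without 1 library (those without YP3, AN1, AN3 or AP2, with -0.29 without AP2). Emx1, a transcription factor of cortical excitatory neurons, averaged 354 ± 103 against 525 ± 124, and Cux1 ran the other way, at 1710 ± 41.7 against 1270 ± 359. With the olfactory bulb score as a covariate the calls of cholinergic (-0.09, adjusted p = 0.17), excitatory (-0.09, adjusted p = 0.25), glucocorticoid responsive (0.09, adjusted p = 0.24) and heat shock genes (-0.15, adjusted p = 0.14) ended. In the fit that left out YP2, AP1 and AP3 those of cholinergic (-0.34, adjusted p = 0.25), excitatory (-0.1, adjusted p = 0.54), glucocorticoid responsive (0.15, adjusted p = 0.31) and meningeal genes (0.24, adjusted p = 0.54) ended. The title prefix as a covariate ended those of cholinergic (-0.18, adjusted p = 0.098), glucocorticoid responsive (0.09, adjusted p = 0.3), meningeal (0.52, adjusted p = 0.51), excitatory (-0.16, adjusted p = 0.35) and, among the lists that rose above, interferon response genes (0.22, adjusted p = 0.21). Under quantile normalization respiratory chain (-0.08, adjusted p = 0.37), excitatory (-0.16, adjusted p = 0.26) and meningeal genes (0.49, adjusted p = 0.076) lost theirs.

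The 5 genes with the smallest p for age in performing rats were Tlr8, Scin, Pcdh12, RT1-M6-2 and Tmem114. Tlr8, a receptor for single-stranded RNA, averaged 19.9 ± 6.67 in aged against 4.23 ± 1.52 in young performing rats (SD, n = 3), and Scin, an actin-severing protein, 162 ± 97.5 against 18 ± 23.3. Pcdh12, a protocadherin of endothelial cells, averaged 12.6 ± 0.636 against 50.8 ± 25.8, the MHC class I gene RT1-M6-2 10.9 ± 3.7 against 77.5 ± 17.2, and Tmem114 51.6 ± 25.6 against 123 ± 41.4. Changes of Fos, Arc, Egr1, Npas4 and Bdnf lay at 0.3, 0.02, -0.24, 0.15 and -0.36, and those of Gfap and Mbp at 0.87 and -0.13, and none of these genes passed. Of 13496 genes tested in limma, 0 passed (smallest adjusted p = 0.894), and 466 had an unadjusted p under 0.05 where 675 were due by chance. In edgeR and DESeq2 the count was 0, and members passing when adjusted over the list alone numbered 0. With YP2, AP1 and AP3 left out, which leaves AP2 as the lone aged performing library, assumed to vary like the other groups, limma called 0 with 382 genes at an unadjusted p under 0.05.

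Age changes in nonperforming and performing rats shared a sign in 69.4% of genes (Pearson's r 0.37, Spearman's rho 0.49, genes not independent). Each comparison has a young library high on the first component (YN3, YP3), which could give this.

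The average effect of performance asked which genes differed between the 6 performing and the 6 nonperforming libraries, whatever their age. The genes with the smallest p were nearly silent in nonperforming rats. Scin (ENSRNOG00000004498) averaged 18 ± 23.3 and 162 ± 97.5 in young and aged performing rats against 0.321 ± 0.556 and 1.04 ± 0.993 in young and aged nonperforming rats (SD, n = 3). S100a5 (ENSRNOG00000011748), a calcium-binding protein of olfactory sensory neurons, averaged 146 ± 216 and 581 ± 665 against 0.256 ± 0.443 and 3.45 ± 3.04. Ms4a15 averaged 109 ± 166 and 289 ± 186, was listed at 0 in young and stood at 1.48 ± 1.78 in aged nonperforming rats. Klkb1, the gene of plasma prekallikrein, averaged 7.7 ± 9.78 and 18.4 ± 7.76 while listed at 0 in both nonperforming groups. Ly6g6e averaged 53.1 ± 60.1 and 144 ± 116 against 4.32 ± 2.27 and 6.82 ± 1.83. Within the performing groups S100a5 followed the libraries with bulb RNA, at 395, 392.9 and 1319 in YP2, AP1 and AP3 against 28.58 in YP1, 14 in YP3 and 29.65 in AP2, whereas Scin was highest in AP2 (265.7).

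Meningeal and fibroblast genes rose as a list in performing rats, by 1.11 with 14 of 14 higher (adjusted p = 3.5e-06, and adjusted p = 0.59 with an estimated correlation). Slc47a1, an organic cation transporter, passed when adjusted over the list alone, against 0 over all genes tested, and averaged 16.8 ± 11.6 and 39.3 ± 24.2 in performing against 6.16 ± 3.39 and 4.22 ± 3.7 in nonperforming rats. This list was highest in YP2, AP1 and AP3. Its median was 0.68 without YP2 and 0.17 without those 3 libraries (adjusted p = 0.21), and with the olfactory bulb score as a covariate it was -0.32 (adjusted p = 0.0019). Presynaptic vesicle genes fell by 0.24 with 24 of 26 lower (adjusted p = 6.4e-05, and adjusted p = 0.59 with an estimated correlation). They kept that call without any 1 library and lost it under quantile normalization (-0.14, adjusted p = 0.1). Dnm1, the GTPase that pinches off synaptic vesicles, averaged 27900 ± 4520 and 21800 ± 3000 in young and aged performing against 33600 ± 1830 and 32600 ± 5550 in young and aged nonperforming rats. The active zone scaffold gene Bsn averaged 10100 ± 919 and 10100 ± 1550 against 12200 ± 249 and 12800 ± 993. Without YP2, AP1 and AP3 the median of these genes was -0.11 (adjusted p = 0.015), and with the bulb score as a covariate -0.04 (adjusted p = 0.22). Mitochondrially encoded genes rose by 0.46 with 13 of 13 higher (adjusted p = 0.00018, and adjusted p = 0.59 with an estimated correlation), and the median was 0.28 without YN3, 0.33 without the 3 bulb-rich libraries and 0.17 under quantile normalization (adjusted p = 0.039). The call ended in the fit without those 3 libraries and YN3 (0.16, adjusted p = 0.095). COX3, a subunit of cytochrome oxidase, averaged 746000 ± 73300 and 805000 ± 182000 against 619000 ± 27600 and 569000 ± 96400.

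Glutamate receptor genes fell by 0.21 in performing rats with 19 of 22 lower (adjusted p = 0.0038, and adjusted p = 0.69 with an estimated correlation). That call was lost without YN1 (-0.09) or YN2 (-0.08). Grin1, the obligatory subunit of NMDA receptors, averaged 11100 ± 1700 and 8510 ± 206 in young and aged performing against 12700 ± 1450 and 11900 ± 1850 in young and aged nonperforming rats. Grin2b averaged 380 ± 81.9 and 463 ± 28.3 against 641 ± 67.8 and 535 ± 113. Cholinergic genes fell by 0.27 with 13 of 17 lower (adjusted p = 0.0016, and adjusted p = 0.59 with an estimated correlation). Chrna4, a nicotinic receptor subunit, passed when adjusted over the list alone, against 0 over all genes tested, and averaged 1130 ± 153 and 1020 ± 319 against 1540 ± 118 and 1520 ± 164. Excitatory neuron markers fell by 0.22 with 12 of 18 lower (adjusted p = 0.033, and adjusted p = 0.59 with an estimated correlation). The list lost its call without YN1 (-0.16), YN2 (-0.19), YP3 (-0.21), AN1 (-0.14) or AP3 (-0.21). Neurod6 averaged 1730 ± 508 and 1170 ± 438 against 2200 ± 161 and 2190 ± 446, whereas Cux1 ran the other way. These 3 neuronal lists were nearer 0 without YP2, AP1 and AP3, at -0.12 for glutamate receptor (adjusted p = 0.01), -0.12 for cholinergic (adjusted p = 0.015) and -0.07 for excitatory genes (adjusted p = 0.24). With the bulb score as a covariate they were at -0.07 (adjusted p = 0.049), -0.17 (adjusted p = 0.099) and -0.02 (adjusted p = 0.75) in that order, so that cholinergic and excitatory genes lost their calls. Excitatory genes also lost theirs under quantile normalization (-0.15, adjusted p = 0.13).

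Senescence and cell cycle inhibitor genes rose by 0.24 with 16 of 18 higher (adjusted p = 0.00064, and adjusted p = 0.59 with an estimated correlation), and without YP2, AP1 and AP3 the median was 0.17 (adjusted p = 0.008), whereas with the bulb score as a covariate the call ended (0.11, adjusted p = 0.058). Its leading members included secreted proteins rather than cell cycle inhibitors, such as the chemokine gene Ccl2 (7.77 ± 2.47 and 13.8 ± 2.7 against 3.34 ± 1.35 and 6.62 ± 4.28) and the growth factor binding protein gene Igfbp5 (3040 ± 1520 and 5190 ± 2960 against 1670 ± 147 and 2460 ± 1160). Extracellular matrix genes rose by 0.26 with 22 of 28 higher (adjusted p = 0.0016, and adjusted p = 0.69 with an estimated correlation). Its call was lost without YN3 (0.21) and was 0.06 without the 3 bulb-rich libraries (adjusted p = 0.92). In that list Lamb1, a laminin chain, ran the other way, at 624 ± 115 and 450 ± 66.3 against 745 ± 95 and 683 ± 155. Astrocyte markers rose by 0.22 with 14 of 14 higher (adjusted p = 0.0051, and adjusted p = 0.59 with an estimated correlation), and the median was 0.12 without the 3 bulb-rich libraries (adjusted p = 0.28). Glul, the glutamine synthetase gene, averaged 63300 ± 12500 and 79600 ± 17400 against 55200 ± 5500 and 60200 ± 5700, and the change of Gfap was 0.41. Blood cell genes fell by 1.1 with 8 of 8 lower (adjusted p = 0.0057, and adjusted p = 0.69 with an estimated correlation). The call ended without YN3 (-0.52), AN3 (-0.47), AP2 (-1.02) or the 3 bulb-rich libraries and YN3 (-0.46). Complement and antigen presentation genes rose by 0.28 with 28 of 31 higher (adjusted p = 0.011, and adjusted p = 0.84 with an estimated correlation). This call ended without YN1 (0.29), YN2 (0.29), YP3 (0.24), AN1 (0.13) or AP2 (0.04) and reached 0.49 without YN3, 0.49 without AN3 and 0.47 without AP1. Microglia markers rose by 0.24 with 17 of 18 higher (adjusted p = 0.047, and adjusted p = 0.84 with an estimated correlation). The list lost its call without YN1 (0.2), YN2 (0.22), YP3 (0.14), AN1 (0.12), AN2 (0.23) or AP2 (0.05) and was 0.38 without YN3. The same covariate ended the calls of matrix (-0.08, adjusted p = 0.092) and astrocyte genes (0.09, adjusted p = 0.74), while complement (0.63) and microglia genes (0.45) were higher with it, and at 0.74 and 0.51 without YP2, AP1 and AP3.

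The limma test passed 0 of 13496 genes for performance (smallest adjusted p = 0.0768, for Scin), and 1368 had an unadjusted p under 0.05 where 675 were due by chance (748 higher and 620 lower). At that p 15 of 100 splits of the libraries gave as many as 1368 genes. In edgeR the count was 0 for performance. DESeq2 called 114 (92 higher), and limma with library quality weights, which gave YN2 a weight of 5.69 and YN3 a weight of 0.06, called 2837 (1223 higher). Scin and Ms4a15 passed in limma without YP1, and Scin alone without YP2. With YP2, AP1 and AP3 left out limma called 0, with 229 genes at an unadjusted p under 0.05, and with the bulb score as a covariate it called 0, with 96. Bdnf, a growth factor of activity-dependent plasticity, averaged 437 ± 93.9 and 345 ± 108 in performing against 619 ± 37.9 and 536 ± 162 in nonperforming rats (adjusted p = 0.48), and the changes of Fos, Arc, Egr1 and Npas4 were 0.2, 0.44, -0.23 and 0.1.

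**Figure D3:**
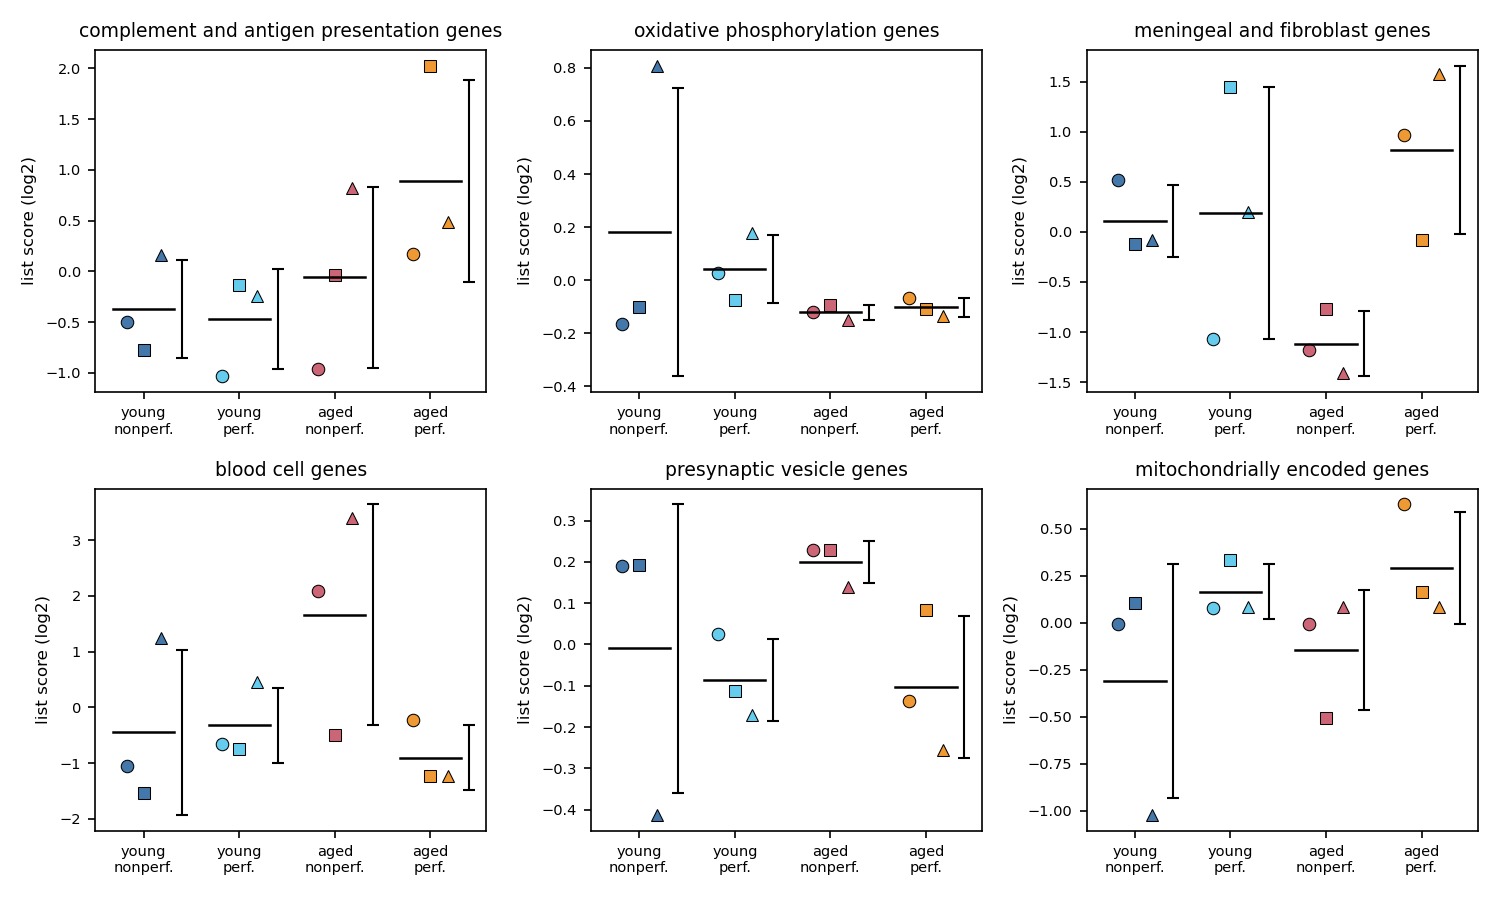
Scores of 6 gene lists by group, as the mean over the members of the log2 value minus the gene's mean over all 12 libraries. Points are libraries (circle, square and triangle for replicates 1, 2 and 3), lines are group means and bars 1 SD (n = 3), and AP2 stands at 2.03 for the complement list, YN3 at 0.809 for the respiratory chain list and -1.02 for the mitochondrially encoded list.

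Performance was then compared within young rats, the contrast of training with no training early in life. Mitochondrially encoded genes rose as a list in young performing rats, by 0.47 with 13 of 13 higher (adjusted p = 0.00026, and adjusted p = 0.86 with an estimated correlation), but the call ended without YN3 (0.14), and without YN3 and the 3 bulb-rich libraries (0.07). Under quantile normalization the median was 0.13 (adjusted p = 0.014). ND4, a subunit of complex I, averaged 423000 ± 38800 in young performing against 296000 ± 137000 in young nonperforming rats (SD, n = 3). Mature oligodendrocyte and myelin genes rose by 0.26 with 23 of 23 higher (adjusted p = 0.0025, and adjusted p = 0.86 with an estimated correlation). Its call was lost without YN1 (0.1), YN2 (0.08) or YP3 (0.16) and was 0.52 without YN3. Sox10, the transcription factor of the oligodendrocyte lineage, averaged 1730 ± 171 against 1240 ± 72.6, and Mbp 150000 ± 22000 against 133000 ± 111000. Senescence and cell cycle inhibitor genes rose by 0.13 with 14 of 18 higher (adjusted p = 0.0025, and adjusted p = 0.86 with an estimated correlation). The call ended without YN1 (0.12), YN2 (0.17) or YP3 (0.09) and was 0.3 without YN3 or YP1. Senescence genes also lost their call with the bulb score as a covariate (0.11, adjusted p = 0.098).

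Nuclear respiratory chain genes fell by 0.15 in young performing rats with 36 of 42 lower (adjusted p = 0.012, and adjusted p = 0.86 with an estimated correlation). The direction turned without YN3 (0.19, adjusted p = 3.5e-09), the call ended without YP2 (-0.08), and the median was -0.32 without YN1, -0.31 without YN2 and -0.24 without YP3. Cox8a ran against the list, at 10800 ± 399 against 9560 ± 150. Presynaptic vesicle genes fell by 0.12 with 19 of 26 lower (adjusted p = 0.021, and adjusted p = 0.86 with an estimated correlation). This call ended without YN1 (-0.02), YN2 (-0.04), YP2 (-0.08) or YP3 (-0.06) and was -0.23 without YN3. Quantile normalization gave -0.01 (adjusted p = 0.99). Glucocorticoid responsive genes rose by 0.14 with 17 of 21 higher (adjusted p = 0.023, and adjusted p = 0.86 with an estimated correlation). The list lost its call without YN1 (0.06), YN2 (0.13), YP2 (0.14) or YP3 (0.12) and was 0.31 without YN3 or YP1. Pdk4 averaged 115 ± 33.2 against 60.9 ± 8.82. These 3 lists lost their calls with the bulb score as a covariate, at -0.12 for respiratory chain (adjusted p = 0.094), 0.02 for presynaptic (adjusted p = 0.93) and 0.06 for glucocorticoid responsive genes (adjusted p = 0.81). They also lost them without YP2, AP1 and AP3, at -0.08 (adjusted p = 0.29), -0.08 (adjusted p = 0.12) and 0.14 (adjusted p = 0.2). Respiratory chain genes were at -0.03 under quantile normalization (adjusted p = 0.79).

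The 5 genes with the smallest p in young rats were Tnk1, Ap1s3, Grin2b, Ms4a15 and S100a5. Tnk1, a tyrosine kinase, averaged 1.67 ± 1.96 in performing against 13.3 ± 3.85 in nonperforming rats (SD, n = 3). Ap1s3, a subunit of a vesicle coat adaptor, averaged 96 ± 11.7 against 40.3 ± 15.2, and Grin2b 380 ± 81.9 against 641 ± 67.8. Arc averaged 6200 ± 825 against 3670 ± 3060. Fos averaged 516 ± 58.5 against 358 ± 147, Npas4 353 ± 62.8 against 218 ± 33.6. Egr1 averaged 5790 ± 960 against 6940 ± 3770 and Bdnf 437 ± 93.9 against 619 ± 37.9. The changes of Gfap and Aif1 were 0.31 and -0.2. Of the 13496 genes, 0 passed in limma (smallest adjusted p = 0.997), and 163 had an unadjusted p under 0.05 where 675 were due by chance. Both edgeR and DESeq2 called 0, whereas limma with library quality weights called 144. A single list member, 1 of 709 listed genes tested, passed when adjusted over the list alone. Without YP2, AP1 and AP3 limma called 0, with 46 genes at an unadjusted p under 0.05, and with YN3 left out as well it called 0, with 1074.

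In aged rats the comparison asked how trained rats differed from untrained rats late in life, and the largest list medians of the 6 age and performance contrasts, for blood cell and meningeal genes, lay here. Meningeal and fibroblast genes rose as a list in aged performing rats, by 2.2 with 14 of 14 higher (adjusted p = 1.4e-12, and adjusted p = 0.44 with an estimated correlation), and 8 of them passed when adjusted over the list alone, against 0 over all genes tested. Igf2 averaged 2470 ± 1790 in aged performing against 187 ± 30.4 in aged nonperforming rats (SD, n = 3), Col3a1 522 ± 295 against 87.5 ± 12.2, and the transporter gene Slc6a13 350 ± 250 against 65.7 ± 16.8. AP1 and AP3 carried most of this, with list scores of 0.964 and 1.58 against -0.081 in AP2. In the fit without YP2, AP1 and AP3, which leaves AP2 alone in its group, the median was 1.06 (adjusted p = 7.1e-07), and with the olfactory bulb score as a covariate it was 0.39 (adjusted p = 0.025). Blood cell genes fell by 2.54 with 8 of 8 lower (adjusted p = 1.1e-05, and adjusted p = 0.44 with an estimated correlation), and by 1.33 in the fit without AN3. S100a9 averaged 28.7 ± 13.5 against 672 ± 929, and Slc4a1, the anion exchanger of red cells, 3.36 ± 0.713 against 119 ± 174. Complement and antigen presentation genes rose by 0.72 with 31 of 31 higher (adjusted p = 1.1e-05, and adjusted p = 0.57 with an estimated correlation). Its call was lost without AP2 (0.25) and was 0.4 without AN1. B2m averaged 19000 ± 4320 against 11800 ± 3230. Microglia markers rose by 0.52 with 17 of 18 higher (adjusted p = 0.001, and adjusted p = 0.57 with an estimated correlation). The call ended without AP2 (0.12) and was 0.24 without AN1. With AP2 as the lone aged performing library, in the fit without YP2, AP1 and AP3, the complement and microglia medians were 1.52 and 0.99. Aif1 averaged 1290 ± 931 against 589 ± 170.

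Among the lists of neuronal genes, 5 general and 1 striatal list fell in aged performing rats, whereas GABA receptor, postsynaptic, interneuron, monoamine and neurotrophin genes did not pass. Presynaptic vesicle genes fell by 0.35 with 23 of 26 lower (adjusted p = 1.9e-05, and adjusted p = 0.44 with an estimated correlation), and Nsf, the ATPase that recycles fusion complexes, averaged 17200 ± 2700 against 24700 ± 3260. Cholinergic genes fell by 0.48 with 14 of 17 lower (adjusted p = 0.00067, and adjusted p = 0.44 with an estimated correlation), with Chrm3, a muscarinic receptor, at 930 ± 255 against 1520 ± 354 and Chat at 8.04 ± 4.36 against 25.2 ± 1.87. Chrnb3 ran the other way at 26.9 ± 18 against 0.648 ± 0.561. Glutamate receptor genes fell by 0.29 with 20 of 22 lower (adjusted p = 0.0026, and adjusted p = 0.57 with an estimated correlation), with Grik4 at 624 ± 36.7 against 877 ± 115. Excitatory neuron markers fell by 0.3 with 12 of 18 lower (adjusted p = 0.0061, and adjusted p = 0.45 with an estimated correlation), and by 0.12 in the fit without AN1. Slc17a7, the vesicular glutamate transporter of cortical neurons, averaged 26100 ± 3890 against 37100 ± 6190. Calcium channel, store and buffer genes fell by 0.33 with 20 of 29 lower (adjusted p = 0.0061, and adjusted p = 0.63 with an estimated correlation), with the channel subunit gene Cacna2d3 at 1390 ± 532 against 2680 ± 666. The calcium buffer gene Calb2 ran the other way at 1560 ± 965 against 236 ± 65.5. With YP2, AP1 and AP3 left out these medians were -0.17 for presynaptic (adjusted p = 0.048), -0.25 for cholinergic (adjusted p = 0.024), -0.14 for glutamate receptor (adjusted p = 0.046), -0.15 for excitatory (adjusted p = 0.19) and -0.16 for calcium genes (adjusted p = 0.088). With the bulb score as a covariate they were -0.13, -0.18, -0.14, -0.09 and -0.2 in that order, and the call of excitatory genes ended (adjusted p = 0.24). Quantile normalization ended the call of calcium genes (-0.25, adjusted p = 0.17). Striatal projection neuron genes fell by 0.64 with 11 of 12 lower (adjusted p = 0.004, and adjusted p = 0.57 with an estimated correlation). This call ended without AN3 (-0.37), the library with high Drd2. Drd1 averaged 106 ± 35.6 against 296 ± 132. Immediate early genes fell by 0.25 with 26 of 36 lower (adjusted p = 0.004, and adjusted p = 0.61 with an estimated correlation). The list lost its call without AN1 (-0.18) or AN2 (-0.07) and was -0.52 without AN3. Fos averaged 636 ± 58.6 against 865 ± 538, Npas4 392 ± 66 against 722 ± 516. Arc averaged 6400 ± 1500 against 7900 ± 3580, Egr1 4890 ± 487 against 6490 ± 2500 and Bdnf 345 ± 108 against 536 ± 162.

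The other lists that rose in aged performing rats were those of astrocyte, choroid plexus, matrix, mitochondrially encoded and senescence genes. Astrocyte markers rose by 0.27 with 14 of 14 higher (adjusted p = 0.0026, and adjusted p = 0.47 with an estimated correlation), with the gap junction gene Gja1 at 15200 ± 1880 against 11800 ± 1480 and Gfap at 30700 ± 7040 against 25300 ± 19400. Choroid plexus markers rose by 1.22 with 9 of 10 higher (adjusted p = 0.012, and adjusted p = 0.61 with an estimated correlation), and by 0.76 without AP3. In that list the potassium channel gene Kcnj13 passed when adjusted over the list alone, against 0 over all genes tested, at 41.9 ± 24.6 against 0.636 ± 1.1. Extracellular matrix genes rose by 0.37 with 21 of 28 higher (adjusted p = 0.0012, and adjusted p = 0.57 with an estimated correlation). Its call was lost without AP3 (0.32) and was 0.18 without AN2, and Nid1, a basement membrane protein, averaged 630 ± 451 against 162 ± 25.8. Mitochondrially encoded genes rose by 0.46 with 13 of 13 higher (adjusted p = 0.004, and adjusted p = 0.57 with an estimated correlation). The call ended without AN2 (0.26) or AP1 (0.28). Under quantile normalization the median was 0 (adjusted p = 0.24). Senescence and cell cycle inhibitor genes rose by 0.24 with 16 of 18 higher (adjusted p = 0.004, and adjusted p = 0.44 with an estimated correlation), with the cell cycle inhibitor gene Cdkn2b at 58.9 ± 31.3 against 17.6 ± 9.7. Without YP2, AP1 and AP3 the 5 calls all ended, with medians of 0.16 for astrocyte (adjusted p = 0.19), 0.31 for choroid plexus (adjusted p = 0.23), 0.12 for matrix (adjusted p = 0.96), 0.32 for mitochondrially encoded (adjusted p = 0.1) and 0.11 for senescence genes (adjusted p = 0.19). With the bulb score as a covariate 4 of them ended, at 0.08 for astrocyte (adjusted p = 0.39), 0.21 for choroid plexus (adjusted p = 0.56), -0.02 for matrix (adjusted p = 0.45) and 0.09 for senescence genes (adjusted p = 0.22), while mitochondrially encoded genes kept theirs (0.3, adjusted p = 0.013). Quantile normalization ended the call of choroid plexus genes (0.82, adjusted p = 0.061).

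Single genes with the smallest p in aged rats were Scin, Ms4a15, Klkb1, Gcnt1 and Cyp39a1. Scin averaged 162 ± 97.5 in performing against 1.04 ± 0.993 in nonperforming rats (SD, n = 3), Ms4a15 289 ± 186 against 1.48 ± 1.78, and Klkb1 18.4 ± 7.76 while listed at 0 in nonperforming rats. Gcnt1, a glycosyltransferase, averaged 337 ± 124 against 115 ± 24.6, and Cyp39a1, an oxysterol hydroxylase, 205 ± 164 against 16.5 ± 3.15. Tested with limma, 0 of 13496 genes passed (smallest adjusted p = 0.138), and 1277 had an unadjusted p under 0.05 where 675 were due by chance (726 higher and 551 lower). In edgeR the count was 0 in aged rats. DESeq2 called 89 (76 higher), and limma with library quality weights called 1347 (621 higher). Scin and Ms4a15 passed in limma without YP2, a library outside this comparison that enters through the shared spread. With YP2, AP1 and AP3 left out, which leaves AP2 as the lone aged performing library, assumed to vary like the other groups, limma called 0 with 345 genes at an unadjusted p under 0.05. Performance changes in young and aged rats shared a sign in 66.6% of genes (Pearson's r 0.46, Spearman's rho 0.42). Bulb-rich libraries, performing at both ages, could give this.

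The interaction asked whether the age effect differed between performing and nonperforming rats. The smallest camera p belonged to meningeal and fibroblast genes, whose median age change was -1.22 in nonperforming and 0.61 in performing rats (interaction 1.95 with 14 of 14 members positive, adjusted p = 9.1e-15, and adjusted p = 0.53 with an estimated correlation). Blood cell genes went the opposite way by a larger amount, with age changes of 1.96 and -0.91 (interaction -2.52, adjusted p = 9.9e-08, and adjusted p = 0.53 with an estimated correlation). Complement and antigen presentation genes had age changes of 0.17 and 0.92 (interaction 0.83 with 31 of 31 positive, adjusted p = 8.8e-09, and adjusted p = 0.53 with an estimated correlation). The interaction of these genes was 0.46 without YN3, 0.49 without AN1 and 0.31 without AP2. Immediate early genes had age changes of 0.31 and 0.03 (interaction -0.36 with 29 of 36 negative, adjusted p = 1.3e-06, and adjusted p = 0.53 with an estimated correlation), with values of -1.5 for Dusp1 and -1.32 for Arc. Their interaction was -0.6 without YN3 and -0.56 without AN3. Fos, Npas4, Egr1 and Bdnf had interactions of -0.79, -1.19, -0.18 and -0.11, and Gfap, Mbp and Aif1 of 0.2, -0.26 and 1.13. Among single genes Cnn1, the calponin of smooth muscle, averaged 13.9 ± 1.3 and 10.8 ± 7.07 in young nonperforming and young performing rats and 6.27 ± 2.2 and 23.6 ± 3.78 in aged nonperforming and aged performing rats (SD, n = 3). Clic3 averaged 25.9 ± 6, 17 ± 7.2, 11 ± 3.13 and 28.8 ± 0.749 in that order of groups, Dnase1 10.3 ± 4.95, 2.63 ± 4.55, 1.61 ± 1.47 and 9.75 ± 3.59, and Tnk1 13.3 ± 3.85, 1.67 ± 1.96, 5.33 ± 3.66 and 7.38 ± 2.51. Lgals5, a galectin of rat red cells, averaged 8.74 ± 7.28, 16 ± 6.23, 57.7 ± 66.7 and 3.79 ± 3. By limma, 0 of 13496 genes passed (smallest adjusted p = 1), and 139 had an unadjusted p under 0.05 where 675 were due by chance. The counts by edgeR and DESeq2 were 0. A total of 15 of the 34 lists passed with the preset correlation, with 0 members passing when adjusted over the list alone. Without YP2, AP1 and AP3 limma called 0, with 236 genes at an unadjusted p under 0.05.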

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

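Of the tests below, those of the choroid plexus genes, of the RT1 genes and of all gene counts over regrouped libraries (also at an unadjusted p) were chosen only after the result was seen. The tests of the olfactory bulb score and of transcript length use gene lists added after the data were seen. Each difference of the age effect between performing and nonperforming rats that passed as a list drew attention because the groups differ. Meningeal and fibroblast genes had an interaction of 1.95, complement and antigen presentation genes of 0.83, blood cell genes of -2.52 and immediate early genes of -0.36, as described above. Choroid plexus markers had 1.53 (adjusted p = 7.1e-06, and adjusted p = 0.53 with an estimated correlation), which ended without YN3 (0.02) and was 2.65 without YN1. Striatal projection neuron genes had -0.88 (adjusted p = 7.1e-06, and adjusted p = 0.53 with an estimated correlation), which was -0.44 without YP3 and -0.56 without AN3. Microglia markers had 0.62 (adjusted p = 4.1e-05, and adjusted p = 0.53 with an estimated correlation), which ended without AP2 (0.22) and was 0.35 without YN3 and 0.41 without YP1. Calcium channel, store and buffer genes had -0.3 (adjusted p = 0.0065, and adjusted p = 0.69 with an estimated correlation), which ended without YN3 (0.09) or AN1 (-0.24) and was -0.18 without YP1. Presynaptic vesicle genes had -0.21 (adjusted p = 0.0097, and adjusted p = 0.55 with an estimated correlation), which ended without YN3 (-0.05) or AP3 (-0.15).

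Mature oligodendrocyte and myelin genes had an interaction of -0.28 (adjusted p = 0.014, and adjusted p = 0.79 with an estimated correlation), which ended without YN1 (-0.16), YN2 (-0.18), YP3 (-0.19), AN2 (-0.15), AN3 (-0.04), AP2 (-0.29) or AP3 (-0.16) and was -0.59 without YN3 and -0.71 without AN1. Cholinergic genes had -0.35 (adjusted p = 0.017, and adjusted p = 0.53 with an estimated correlation), which ended without YN3 (-0.19), YP3 (-0.23), AN2 (-0.16) or AP3 (-0.23). Excitatory cortical neuron markers had -0.11 (adjusted p = 0.032, and adjusted p = 0.53 with an estimated correlation), which ended without YN3 (-0.19), YP1 (-0.16), YP3 (-0.23), AN1 (-0.12) or AP3 (-0.11) and was -0.19 without YN1, -0.22 without YN2, -0.24 without YP2, -0.17 without AN2, -0.18 without AN3, -0.17 without AP1 and -0.19 without AP2. Oxidative phosphorylation genes had 0.15 (adjusted p = 0.033, and adjusted p = 0.79 with an estimated correlation), which turned without YN3 (-0.16), ended without YP2 (0.08), AN1 (0.16), AN3 (0.13), AP1 (0.13) or AP2 (0.15) and was 0.35 without YN1, 0.31 without YN2 and 0.25 without YP3. Antioxidant and metal binding genes had 0.2 (adjusted p = 0.033, and adjusted p = 0.59 with an estimated correlation), which ended without YN3 (-0.04), YP1 (0.16), YP2 (0.26), AN1 (0.18), AN2 (0.13), AP1 (0.2) or AP3 (0.15) and was 0.4 without YN1, 0.34 without YN2 and 0.34 without AN3. Astrocyte markers had 0.2 (adjusted p = 0.043, and adjusted p = 0.59 with an estimated correlation), which ended without YN2 (0.24), YN3 (0.15), YP1 (0.19), YP3 (0.07), AN1 (0.18), AN2 (0.16) or AP1 (0.11) and was 0.34 without YP2. In the fit without YP2, AP1 and AP3 together, 7 of the 15 interaction calls ended, at -0.09 for presynaptic (adjusted p = 0.41), -0.17 for calcium (adjusted p = 0.21), -0.18 for cholinergic (adjusted p = 0.21), -0.13 for excitatory (adjusted p = 0.3), 0.07 for oxidative phosphorylation (adjusted p = 0.72), 0.09 for antioxidant (adjusted p = 0.5) and 0.17 for astrocyte genes (adjusted p = 0.31). With the olfactory bulb score as a covariate 5 ended, at -0.11 for presynaptic (adjusted p = 0.1), -0.24 for cholinergic (adjusted p = 0.11), -0.12 for excitatory (adjusted p = 0.097), 0.17 for antioxidant (adjusted p = 0.097) and 0.1 for astrocyte genes (adjusted p = 0.29).

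Genes that differed between performing and nonperforming rats may owe their difference to olfactory bulb tissue in some performing libraries, to sequencing depth, or to performance itself. Over the 741 genes higher in performing rats at an unadjusted p under 0.05 that could be followed, the median correlation with the bulb score across the 6 performing libraries, centred within age, was 0.82, and over the 620 lower genes it was -0.8, against -0.04 for all genes. Score and genes came from these libraries, so bulb tissue stays open. Mean log2 depth in performing rats differed by -0.05, which argues against depth. Thinning to AP1's depth left 0.98 of the higher genes' median change, a share thinning nearly fixes. With the bulb score as a covariate 0 genes passed (limma, 96 at an unadjusted p under 0.05), and performance stays open, as the 3 bulb-rich libraries were all performing.

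YN3 stood apart from the other libraries, which may come from choroid plexus tissue, from a shift by transcript length, or from biology of that sample. Of the 10 choroid plexus genes tested, 7 were highest in YN3, between the cutoffs of 8 for and 4 against such tissue. The list scored 3.325 in YN3 and 1.283 or less elsewhere, so YN3 was richest in plexus RNA, but its share stays open. The median of 53 ribosomal protein genes lay 1.47 above and that of 39 long transcript genes 1.24 below the other young nonperforming libraries (as -1.24), a difference of 2.71 where the 9 libraries of the other groups ran from -0.29 to 0.35. A shift by transcript length, such as RNA breakdown or a different library preparation could leave, therefore fits YN3. Biology of that sample was not tested.

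The higher complement and antigen presentation list in aged rats may come from Wistar variants in the RT1 genes, from blood in the tissue, or from age itself. The 22 members outside the RT1 genes had a median of 0.55 (0.39 to 0.91 bootstrapping genes, not libraries). Such variants alone would not give that, and the RT1 members (0.97) stay untested. With the blood cell score as a covariate 0.9 of the change remained (0.56 to 0.51). That score holds red cell and neutrophil genes and speaks against those cells only. The median was 0.44 without AP2. Age itself stays open.

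Regrouping the libraries at random tested whether chance could give the counts. For age and for performance the labels were permuted within the levels of the other factor. For the interaction they were shuffled over all 12 libraries, so those splits also mix in the effects of age and of performance. For gene counts the real value was 0 in every contrast, so every split was as large by definition (100 of 100 for age, performance and the interaction, highest others 19, 7 and 21), and the comparison decides nothing. At an unadjusted p under 0.05, 12 of 100 splits gave as many genes as the 1012 for age (highest other 3039), 15 of 100 as many as the 1368 for performance (highest other 3015) and 65 of 100 as many as the 139 for the interaction (highest other 2429), so chance can not be excluded for these counts. With library quality weights, 39 of 100 splits gave as many genes as the 2837 called for performance (highest other 6351), so chance can not be excluded there. Gene lists past the threshold numbered 8 for age, with 82 of 100 splits as large (highest other 23), 12 for performance with 56 of 100 (highest other 20) and 15 for the interaction with 30 of 100 (highest other 23), so chance can not be excluded for these either. Within 1 level of a factor only 10 splits exist, too few for a share under 0.05. The gene counts there were 0, with 10 of 10 as large by definition and highest others of 19 for age in nonperforming rats, 64 for age in performing rats and 0 for performance in young and in aged rats. List counts there were 8 for age in nonperforming rats (7 of 10 as large, highest other 19), 11 for age in performing rats (6 of 10, highest other 15), 6 for performance in young rats (9 of 10, highest other 22) and 16 for performance in aged rats (2 of 10, highest other 21).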

How the results depend on the processing

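The alternatives without YP2, AP1 and AP3, without these and YN3, with the olfactory bulb score as a covariate, with quantile normalization of lists and with permutation of list scores were tests chosen only after the result was seen, and the others were fixed before the data were examined. Over all alternatives, 304 gene and list counts stayed as they were, 24 were stronger and 27 weaker. Of the list values 1159 kept their call, 486 lost it and 12 turned, and of the named gene values 2476 stayed and 44 came to pass.

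Gene counts were 0 in limma in all 7 contrasts. DESeq2 gave 2 for age, 7 for age in nonperforming rats, 114 for performance and 89 for performance in aged rats. Library quality weights gave 5, 4, 2837, 144 and 1347 for age, age in nonperforming rats, performance, performance in young rats and performance in aged rats. A threshold of 0.1 gave 1 for performance (Scin), and leaving out YP2, AP1, AP3 and YN3 gave 1 for age (Plac8). Without 1 library the counts ran from 0 to 2 for performance and from 0 to 2 for performance in aged rats, and from 0 to 0 in the other 5 contrasts. The cause was not tested for any of these, beyond the weights of 5.69 for YN2 and 0.06 for YN3.

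List counts were 8, 8, 11, 12, 6, 16 and 15 of 34 for age, age in nonperforming rats, age in performing rats, performance, performance in young rats, performance in aged rats and the interaction. With an estimated correlation they were 0 in all 7, and with fry 0 in all 7. The preset leaves out most of the correlation between members across libraries, which accounts for the first drop, and the cause was not tested for fry. Exact permutation gave 0 in the 6 contrasts it was run for. In the 4 contrasts within 1 level of a factor that 0 was fixed by the design, since 3 libraries against 3 allow no p under 0.1, so it says nothing about those lists. In the averaged contrasts 3 lists for age (endothelial, circadian clock and glucocorticoid genes) and 2 for performance (mitochondrially encoded and senescence genes) had an unadjusted permutation p under 0.05, with a smallest p of 0.035 and 0.015, and adjusted p = 0.51 for each. Without 1 library the counts ran from 5 to 13, 7 to 15, 6 to 13, 9 to 17, 3 to 14, 14 to 19 and 11 to 17 in that order. The title prefix as a covariate gave 5 for age and 6 for age in performing rats. The olfactory bulb score as a covariate without YN3 gave 15 for age, 14 for age in nonperforming rats and 14 for performance in young rats. Leaving out YP2, AP1, AP3 and YN3 gave 16 for age in nonperforming rats and 16 for performance in young rats, and leaving out the first 3 of these gave 10 for performance in young rats. The cause was not tested for these counts.

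List values that turned and still passed were these. With the olfactory bulb score as a covariate, meningeal and fibroblast genes were at -0.24 for age in performing rats (-0.24 without YN3 as well) and at -0.32 for performance (-0.41 without YN3 as well), and extracellular matrix genes at -0.24 for performance with the covariate and without YN3. Oxidative phosphorylation genes in young rats by performance were at 0.19 without YN3, 0.26 without YP2, AP1, AP3 and YN3, and 0.23 with the covariate and without YN3. Their interaction (0.15 with all libraries) was -0.16, -0.19 and -0.12 under the same 3 alternatives, and kept its sign at 0.35 without YN1, while that of calcium channel, store and buffer genes was 0.22 without the 4 libraries. The cause was not tested for any value that turned.

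Calls were not counted again after thinning.

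Rescaling by TMM shifted the median gene by 0 to 0.022 and quantile normalization by -0.047 to -0.02. Single lists moved more. Quantile normalization ended 13 of the 76 list calls. The interaction calls among these were of astrocyte (0.16, adjusted p = 0.057) and excitatory genes (-0.12, adjusted p = 0.065), and the other 11 stand beside their lists. TMM ended 2, those of microglia markers for age (adjusted p = 0.052) and for performance (adjusted p = 0.053). The title prefix as a covariate ended 9, 4 for age and 5 for age in performing rats. The cause was not tested for these lists.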

Other observations

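None of the list tests of this part was chosen only after the result was seen, and the values of Gad1 were. Several groups of genes with a known part in attention, plasticity or aging passed in 0 of the 7 contrasts. GABA receptor genes had medians of 0.12 for age and -0.14 for performance, neurotrophin genes of 0.06 and 0.1, monoamine receptor and metabolism genes of 0 and -0.03, and perineuronal net genes, which stabilise inhibitory neurons, of 0.01 and 0.06. Postsynaptic scaffold and adhesion genes had medians of 0.02 for age and -0.06 for performance, cortical interneuron markers of 0.2 and 0.14, circadian clock genes of 0.07 and -0.02, and lysosome genes of 0.07 and 0.04. Chromatin and DNA methylation enzyme genes had medians of 0.1 and 0.1, neuroblast and cell division genes of -0.11 and 0.13, and oligodendrocyte precursor genes of -0.05 and 0.07. The GABA synthesis gene Gad1 stood at 8691 in YP2, 9196 in AP1 and 13940 in AP3, the libraries with the most Cdhr1.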
